A study of Mus musculus with 2 samples.

How the data were processed

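Kidney cells of FVBN mice positive for PDGFR alpha and PDGFR beta were profiled by droplet-based single-cell RNA sequencing (10x Chromium version 2, 3′ end), per the labels. There was 1 library from a sham-operated kidney and 1 from a kidney 10 days after unilateral ureteral obstruction (UUO), as labelled, and groups were taken from the labels alone. Kidneys were digested with enzymes and dissociated mechanically before sorting, per the labels' protocols. Each library came as a matrix of cells by 53698 gene entries with lists of barcodes and genes. The values are expected counts of UMIs per gene and cell, deposited by the authors without normalisation. They were made with alevin of Salmon 0.13.1 on the mm10 genome, per the submitters' processing notes. Alevin shares UMIs that match several genes among them, so values need not be whole. At a tolerance of 1e-06, 92.3% of nonzero values labelled sham and 91.2% labelled UUO were whole. Genes with near-identical copies or overlapping neighbours are uncertain for this reason. How barcodes were chosen before deposit is not given in the sources used here. Of the gene entries, 52806 carry an identifier and version found in GENCODE M21, whose coordinates are used. The entry eGFP is a reporter sequence. All 423 symbols of the fixed gene lists and markers were matched, 2 of them (Ccn1 and Ccn2) by an older symbol.

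The deposited expected counts summed to 85359332 UMIs over 10812 barcodes labelled sham and 6023072 over 1291 labelled UUO. Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrially encoded genes, which left 10656 and 1052. Doublets were scored with a new implementation of Scrublet's score (expected rate 0.06, 2 simulated doublets per cell). The cells with the highest scores were removed, as many as 0.8% per 1000 cells, which took 908 and 9. Values were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and cells of both libraries were clustered together, without integration, by the Leiden method at resolution 1 on 20 nearest neighbours. Cluster names came from markers fixed before the data were examined. The rule that turns markers into names was set after clusters had been seen. A class was named when at least 3 and at least 40% of its markers were 4-fold or more above the other cells (20 CPM added) and in at least 10% of cells. Otherwise a cluster was fibroblast- or myofibroblast-like when at least 3 fibroblast markers were in 25% of its cells and the median log2 ratio of those markers was at least -1. Clusters with a median depth under 0.333 of their library's with no marker of their class among their 10 leading genes stayed unnamed. This gave 28 clusters, 14 of them mesenchymal.

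With 1 library per group, no test between groups was made and no p-value is given. Cells are not replicates. For the gene comparison, expected counts were summed over the mesenchymal cells of each library, rounded to whole numbers and scaled by the summed total to the usual CPM unit. The ratio carries an exact conditional binomial 95% interval, and log2 ratios were taken after adding 5 CPM, which shrinks the ratios of low genes. Shares of cells carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only and say nothing of variation between animals. A count of 0 was set against 3 counts. List medians were taken over members with at least 10 CPM in either library, with an interval from 500 Poisson redraws. Their percentile among 10000 random lists matched on mean CPM describes these 2 libraries. For shares of cells with a UMI, each cell was also thinned to 1000 UMIs and shallower cells were left out. Cells with and without an Nkd2 UMI were compared by the share of their UMIs from the 86 genes of the matrix lists, beside the same difference for genes detected in 0.5 to 2 times as many cells.

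The gene lists, the markers and the rule for named genes were written before the data were examined. The rule took the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM and 50 counts in the higher library. Mitochondrial and ribosomal protein genes and markers of other cell types were left out of it, and 1 gene that met the rule is not used here. Up to 4 members per list were added, the 2 largest and the 2 smallest, and Nkd2, Pdgfra, Pdgfrb, Acta2, Postn and Col1a1 were always named. In the comparison of Nkd2-detecting cells, members of the lists were named after their values were seen. Fold changes in the text are ratios of CPM without the added 5. Counts and shares of genes at least 2-fold or 1.5-fold higher or lower use the ratios with 5 CPM added.

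The gene and list calculations were checked on simulated counts drawn from the pooled profile of 53698 genes at the real totals, with 200 of the 8367 genes at 10 CPM or more changed. Intervals held the true ratio for 95.9% of 8167 unchanged genes. The interval lay on the true side of 1 for 92% of 50 genes changed 1.5-fold and 100% of 50 genes each at 2, 4 and 8-fold. Of 200 lists of unchanged genes, 4.5% lay outside the central 95% of random lists. Simulated counts were drawn independently per gene. The check therefore does not show how often lists of genes that vary together reach extreme percentiles.

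Alternatives were a UMI minimum of 1000, a mitochondrial limit of 10%, no doublet removal, no cell filter, resolutions of 0.5 and 2, each library clustered on its own, median-of-ratios scaling, equal weight for each cell, thinning to 1000 UMIs, added values of 1 and 20 CPM, all retained cells, fibroblast-like cells only, totals without mitochondrial and ribosomal genes, and no filter on list members. Added after the data were seen were cells with Xist or with Y-linked UMIs only, genes of other cell types left out of the total, clusters 7 and 8 counted as mesenchymal, and Spp1 left out of the matrix genes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.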

Results

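Single-cell RNA profiles were collected from mouse kidney cells carrying the PDGF receptors alpha and beta, surface proteins used to sort fibroblasts, pericytes and related stromal cells. The cells came from FVBN mice, and libraries were made with droplet-based 3′ chemistry that tags each captured transcript with a unique molecular identifier (UMI). There were 2 libraries, 1 labelled sham and 1 labelled UUO, for unilateral ureteral obstruction, a surgical model of kidney fibrosis, with the kidney taken 10 days after the operation. With 1 library per group there is no replicate check, no test between groups was made, and every interval covers counting error only. The library labelled sham held 10812 barcodes, with a median of 7740.5 UMIs and 2869 genes per barcode. The library labelled UUO held 1291 barcodes, with a median of 3088 UMIs and 1567 genes. After filtering, 9748 and 1043 cells were retained, with medians of 7427 and 4139 UMIs. Some transcripts known to go with kidney injury and fibrosis, such as Spp1 and Timp1, were higher in the library labelled sham, and others, such as Ccn2, Postn and C3, in the library labelled UUO. Because part of them ran against the labels, both groups are named as labelled throughout, and no direction is given as an effect of obstruction.

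The first comparison concerned which cell types the sorted cells held. Mesenchymal cells were the largest class of each library, and the library labelled sham held a larger share of macrophage-like cells while the library labelled UUO held a larger share of proximal tubule- and endothelial-like cells. Fibroblast- or myofibroblast-like cells were 74.9% (95% exact binomial CI 74.0 to 75.8) of the library labelled sham and 62.2% (59.2 to 65.2) of the library labelled UUO. Pericyte- or smooth muscle-like cells, in a cluster led by the renin gene Ren1 and by Rgs5, numbered 39 in each library, or 0.4001% (0.285 to 0.547) and 3.74% (2.67 to 5.08). Together these mesenchymal cells were 75.3% (74.4 to 76.2) and 66.0% (63.0 to 68.8), the latter 44.9% with each library clustered on its own. Cluster 15, 13.9% of the library labelled UUO, was left out as erythroid-like, although 8 fibroblast markers were each in at least 25% of its cells. The order of the 2 mesenchymal shares depends on that name and on clusters 7 and 8, which stayed unnamed. No alternative counted cluster 15 as mesenchymal. Macrophage- or dendritic-like cells, with C1qa, C1qb and Cd74 among their leading genes, were 287 of 9748 cells in the library labelled sham, 2.94% (2.62 to 3.30). They were 2 of 1043 cells in the library labelled UUO, 0.192% (0.0232 to 0.691). Endothelial-like cells were 4.35% (3.95 to 4.77) and 7.48% (5.96 to 9.25). Proximal tubule-like cells, with Miox, Kap and Slc34a1 in the lead, were 0.359% (0.2502 to 0.499) in the library labelled sham and 7.86% (6.30 to 9.66) in the library labelled UUO. T- or NK-like cells were 34 and 2.

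Profiles led by haemoglobin genes fell into clusters 15 and 8, each nearly all of 1 library. Cluster 15, named erythroid-like, held 145 of 1043 cells, 13.9% (11.9 to 16.2), of the library labelled UUO. It held 0 of 9748 cells labelled sham, which allows a share of up to 0.0308% for that cluster alone. Cluster 8, led by Hbb-bs, Hba-a1 and Hbb-bt but left unnamed by the rule, held 547 cells labelled sham, 5.61% (5.16 to 6.09), and 2 labelled UUO. None of the erythroid markers met the rule in it, in a comparison where cluster 15 was among the other cells. No difference in red blood cell content is therefore read. Cluster 15 had a median of 1108 UMIs, and the fibroblast transcripts Clec3b, Igfbp3 and Inmt stood beside the globin genes among its leading genes. Cluster 12, a tubule cluster led by Clu, Lcn2 and Umod, held 239 cells labelled sham and 16 labelled UUO. Its leading genes named another class more often than its own, so it is given by number only. Cluster 19, with cell cycle genes such as Birc5 and Cdc20 beside the immunoglobulin genes Igkc and Igha, held 96 and 2 cells. The shares depend on the sort, on the UMI minimum and on the gap in depth between the libraries. The shallow clusters 7 and 8, led by pseudogenes and haemoglobin genes, stayed unnamed. They held 13.1% of retained cells in the library labelled sham and 0.192% in the library labelled UUO.

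**Figure D1:**
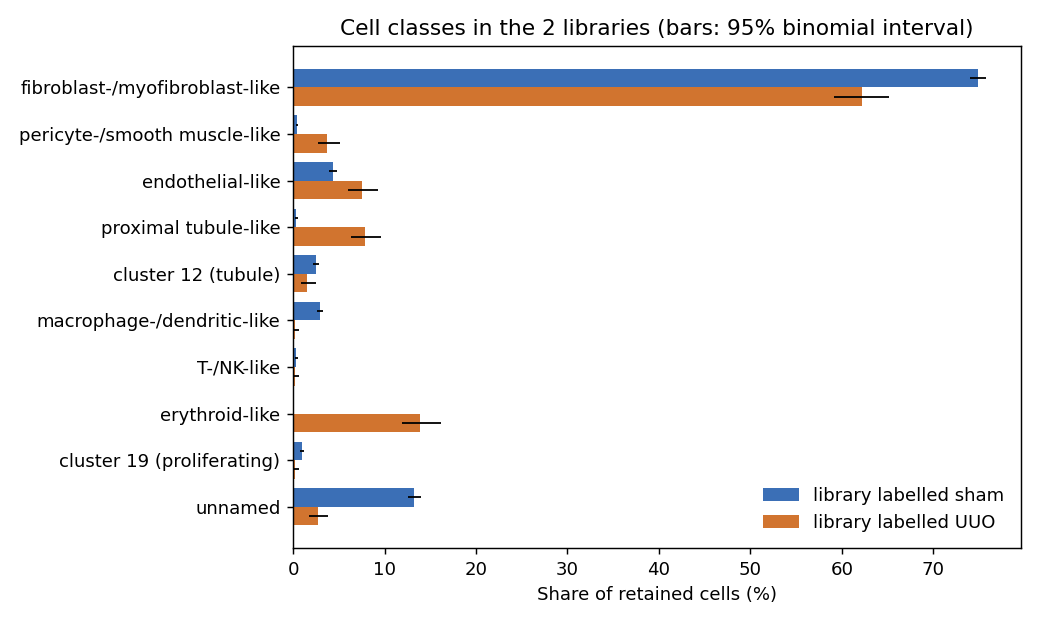
Share of retained cells (%, horizontal axis) in each cell class (vertical axis) for the library labelled sham (blue) and the library labelled UUO (orange), with bars for the 95% exact binomial interval. The cluster named erythroid-like, at 13.9%, appears only in orange, and macrophage-like cells are 2.94% against 0.192%. Cluster 8, led by haemoglobin genes and mostly of cells labelled sham, had no erythroid marker that met the naming rule and is among the unnamed.

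The mesenchymal cells of the libraries fell into different clusters. Clusters 1 to 6, 13, 18, 24 and 28 held 7301 fibroblast-like cells labelled sham, and clusters 10, 11 and 22 held nearly all of those labelled UUO. Among mesenchymal cells, 99.2% of those labelled sham and 94.0% of those labelled UUO sat in clusters made up of at least 99% cells of their own library. Values within the class are compared with that in view, since such a cluster can stand for a library as well as for a cell type.

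The sort named in the labels was checked through the transcripts of the receptors. Each transcript was found in a larger share of mesenchymal than of endothelial-like cells in both libraries. Pdgfra UMIs were detected in 77.6% (76.7 to 78.6) of 7340 mesenchymal cells labelled sham and in 66.9% (63.2 to 70.4) of 688 labelled UUO, at median depths of 8636 and 5501.5 UMIs. In endothelial-like cells, which lack the receptor, the shares were 12.03% (9.09 to 15.5) and 7.69% (2.88 to 15.99), at 3689 and 4433 UMIs. The summed level of Pdgfra went the other way, 236 CPM (counts scaled to a common library total) in the library labelled sham and 255 in the library labelled UUO. After each cell was thinned to 1000 UMIs, the shares were 21.9% (20.9 to 22.8) and 22.3% (19.2 to 25.6), so no order is read from Pdgfra. Pdgfrb UMIs were found in 83.1% (82.3 to 84.0) and 53.6% (49.8 to 57.4) of mesenchymal cells, against 14.2% (10.98 to 17.8) and 8.97% (3.68 to 17.6) of endothelial-like cells. Thinned, the Pdgfrb shares were 27.0% (25.9 to 28.0) and 17.0% (14.2 to 20.1), and the levels were 289 and 185 CPM. Thinning left out 18 mesenchymal cells labelled sham and 24 labelled UUO. Both transcripts were found in the same cell in 65.6% (64.5 to 66.7) of mesenchymal cells labelled sham and 39.2% (35.6 to 43.0) of those labelled UUO, against 2.36% (1.14 to 4.29) and 1.28% (0.0325 to 6.94) of endothelial-like cells. Thinned, the joint shares were 6.597% (6.04 to 7.19) and 5.12% (3.57 to 7.08), with intervals that overlap.

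The main comparison, between obstructed and sham-operated kidneys as labelled, was made on summed counts of the mesenchymal cells, 62932365 UMIs labelled sham and 4370639 labelled UUO. The genes furthest towards the library labelled sham included Nkd2, Alx1, Serpine2 and Timp1, and those furthest towards the library labelled UUO included Inmt, Clec3b and Apod. Nkd2, which binds Dishevelled and dampens WNT signalling, was 18.1-fold (95% CI 13.4 to 25.3) higher in the library labelled sham, at 170 against 9.38 CPM. The activin subunit genes Inhba and Inhbb were 13.9-fold (10.8 to 18.2) and 16.6-fold (10.2 to 29.1) higher. Timp1, an inhibitor of matrix metalloproteinases, was 11.4-fold (10.1 to 12.9) higher and Serpine2, a serine protease inhibitor, 11.4-fold (10.7 to 12.1), the latter at 2489 against 219 CPM. The homeobox gene Alx1 was 15.5-fold (13.0 to 18.6) higher and Rgs16, a regulator of G protein signalling, 12.4-fold (10.4 to 14.9). Further genes on that side were Tnfsf8 and Tnfrsf21, of the TNF ligand and receptor families, at 16.9-fold (10.2 to 30.2) and 13.3-fold (9.38 to 19.6), and the receptor-modifying Ramp3 at 12.4-fold (8.68 to 18.4). Gm14036 was 13.0-fold (10.3 to 16.8) higher, but it is a pseudogene inside Plcb1 on the same strand, so its reads are uncertain.

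Clec3b, the gene of tetranectin, was 101-fold (94.7 to 108) higher in the library labelled UUO, at 1682 against 16.7 CPM. Inmt, a methyltransferase gene, was 245-fold (211 to 287) higher and Fmo2, a flavin monooxygenase gene, 102-fold (90.1 to 115). The lipid and retinol carriers Apod and Rbp4 were 65.8-fold (60.6 to 71.5) and 41.0-fold (38.4 to 43.7) higher, and carbonic anhydrase Car3 52.0-fold (47.9 to 56.5). The chemokine gene Cxcl13 was 52.1-fold (45.6 to 59.7) higher and Sfrp4, a secreted WNT modulator, 30.0-fold (28.6 to 31.4). Car3 was among the leading genes of clusters 22 (44 cells labelled UUO, 0 labelled sham) and 28 (1 and 23). Sfrp4 was among those of clusters 11 (276 and 0) and 13 (1 and 190). Clec3b, Inmt, Fmo2, Apod and Cxcl13 were also among those of cluster 11, and Rbp4 of cluster 22. On the other side, Nkd2, Serpine2 and Timp1 were among those of cluster 4. Alx1 was among those of cluster 3, and Inhba, Ramp3 and Tnfrsf21 of cluster 6. Clusters 3, 4 and 6 held 0 cells labelled UUO. The ratios of all these genes therefore do not separate the level per cell from the share of such cells. Dlk1, an imprinted gene, was counted 694 times in the library labelled UUO and 9 times in the library labelled sham, a ratio of 1110 (582 to 2438). Olfr374, annotated as an olfactory receptor gene, had a ratio of 943 (594 to 1597), from 1179 against 18 counts. E2f1 was 50.04-fold (44.5 to 56.3) and the long noncoding RNA Gm32885 34.8-fold (31.4 to 38.5) higher. All of these genes kept their direction, each by at least 2-fold, under every alternative run on them. Olfr374 and E2f1 were among the leading genes of cluster 10 (327 cells labelled UUO, 0 labelled sham), and Gm32885 of cluster 11. The limit on shares of cells holds for these 3 genes too.

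Among the 9659 genes with at least 10 CPM in either library, the median log2 ratio was 0.01. After adding 5 CPM, at least 2-fold higher values in the library labelled UUO were seen for 13.0% of them, and at least 2-fold lower values for 4.57%. Counts of list members by fold below were also taken after adding 5 CPM. Acta2, the smooth muscle actin of myofibroblasts, was 2.28-fold (2.20 to 2.37) higher in the library labelled sham, at 1521 against 667 CPM. Its log2 ratio moved from -1.18 to -2.17 in fibroblast-like cells only, and to -1.96 and -1.81 in cells with Xist and with Y-linked UMIs. Col1a1, a chain of type I collagen, was 1.56-fold (1.53 to 1.60) higher there. Postn, the gene of periostin, was 1.80-fold (1.65 to 1.95) higher in the library labelled UUO, at 142 against 79.2 CPM, with a log2 ratio of 0.81 that moved to 1.26 with each library clustered on its own and to 0.24 with equal weight for each cell. Pdgfrb was 1.56-fold (1.46 to 1.68) higher in the library labelled sham. With each library clustered on its own, the log2 ratio of Pdgfrb moved from -0.63 to -1.34 and that of Col1a1 from -0.64 to -0.32, and Col1a1 was at -0.43 in cells with Xist UMIs. Pdgfra differed by 1.08-fold (1.02 to 1.15) in favour of the library labelled UUO, a direction that turned in the alternatives with each library clustered on its own and with all retained cells.

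These genes lie at known places on the mouse genome (GENCODE M21 annotation of GRCm38, also called mm10). Nkd2 (ENSMUSG00000021567.15) spans chromosome 13 from 73818534 to 73847631 on the minus strand, and Gm8062 overlaps it on the opposite strand. Pdgfra (ENSMUSG00000029231.15) spans chromosome 5 from 75152292 to 75198215 and Pdgfrb (ENSMUSG00000024620.11) chromosome 18 from 61045150 to 61085061, both on the plus strand. Acta2 (ENSMUSG00000035783.8) spans chromosome 19 from 34241090 to 34255590 on the minus strand. Postn (ENSMUSG00000027750.16) spans chromosome 3 from 54361109 to 54391037 and Col1a1 (ENSMUSG00000001506.10) chromosome 11 from 94936224 to 94953042, on the plus strand. All 6 are protein-coding. Alx1 overlaps another gene model on its own strand, Gm17028, at 0.4 CPM or less. Timp1, Inhba, Ramp3, Rgs16 and Pdgfra overlap annotated genes on the opposite strand, whose reads could be shared if strand was not used in counting.

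**Figure D2:**
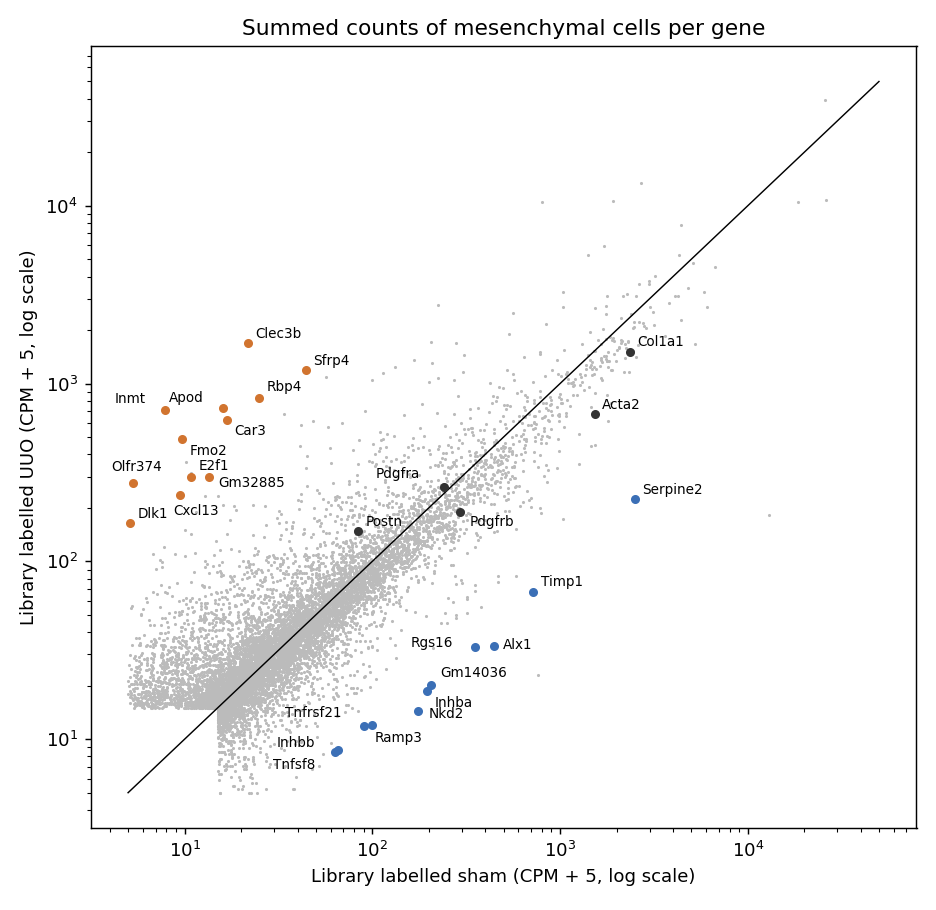
Summed counts of the mesenchymal cells per gene, as CPM + 5 on log axes, in the library labelled sham (horizontal) and the library labelled UUO (vertical), for 9659 genes in grey. Blue and orange points are named genes far to either side, dark points are other genes named in advance, and the line marks equal values. Clec3b, at 1682 against 16.7 CPM, stands far above the line, and Serpine2, at 219 against 2489 CPM, far below it.

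Matrix genes did not move as 1 group. Fibrillar collagens were lower and small proteoglycans higher in the library labelled UUO, with the other matrix lists near the median of all genes or slightly below it. Fibrillar collagens had a median log2 ratio (UUO over sham as labelled) of -0.84 (counting interval -0.91 to -0.75), at the 0.055th percentile of 10000 random lists matched on mean CPM. Of the 7 measured members, 1 was at least 2-fold lower, 5 lay within 2-fold and 1 was at least 2-fold higher. Col5a2 was 5.02-fold (4.48 to 5.64) and Col3a1 1.957-fold (1.91 to 2.00) higher in the library labelled sham, and Col5a3 was 2.64-fold (2.10 to 3.29) higher in the library labelled UUO. Proteoglycans had a median of 2.24 (2.13 to 2.34), above all random lists, with 7 of 10 members at least 2-fold higher and 1 at least 2-fold lower. Lum and Ogn, of the small leucine-rich family that binds collagen fibrils, were 8.44-fold (8.17 to 8.71) and 9.26-fold (8.81 to 9.73) higher in the library labelled UUO. Bgn and Vcan were 1.94-fold (1.90 to 1.98) and 3.69-fold (3.12 to 4.39) higher in the library labelled sham.

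Matrix glycoproteins went both ways, with 6 of 25 members at least 2-fold higher and 8 at least 2-fold lower in the library labelled UUO. Their median was -0.38 (-0.47 to -0.34), at the 3.7th percentile, and -0.60 in cells with Y-linked UMIs. Spp1, the gene of osteopontin, was 72.9-fold (68.0 to 78.3) higher in the library labelled sham, at 13017 against 178 CPM. Ltbp2, whose protein binds fibrillin, was 8.73-fold (5.80 to 13.8) higher there. Ccn2, the connective tissue growth factor, was 4.26-fold (4.10 to 4.43) higher in the library labelled UUO, and Vtn, the gene of vitronectin, 44.8-fold (31.8 to 64.2). Crosslinking and turnover genes had a median of -0.36 (-0.41 to -0.25), at the 2.83rd percentile and -0.17 in cells with Xist UMIs, with 4 of 22 at least 2-fold lower and 2 at least 2-fold higher. The prolyl hydroxylase gene P4ha3 was 27.8-fold (9.49 to 135) higher in the library labelled sham, from 1201 against 3 counts. The aggrecan-cleaving protease gene Adamts5 was 7.82-fold (7.38 to 8.27) and Adamts1 2.61-fold (2.49 to 2.75) higher in the library labelled UUO. Basement membrane genes had a median of 0.09 (0.0077 to 0.21), at the 77.7th percentile, and its sign turned in 3 alternatives. Col15a1 and Col18a1 were 2.82-fold (2.63 to 3.03) and 2.49-fold (2.32 to 2.67) higher in the library labelled sham. Lamb2 was 2.06-fold (1.83 to 2.30) and Col4a5 5.11-fold (3.61 to 7.13) higher in the library labelled UUO.

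Genes of resting fibroblasts were mostly higher in the library labelled UUO. In the quiescent fibroblast list, 11 of 13 members were at least 2-fold higher in the library labelled UUO, with a median log2 ratio of 2.17 (2.14 to 2.23), above all random lists. Scara5, a ferritin receptor gene, was 41.3-fold (34.8 to 49.3) higher and Dpt, a matrix gene of the dermis and fascia, 1.73-fold (1.65 to 1.82), while Sfrp1 was 1.41-fold (1.36 to 1.47) higher in the library labelled sham. Contractile genes had a median of -0.40 (-0.46 to -0.36), at the 5.5th percentile. Counted with 5 CPM added, 5 of 15 were at least 2-fold lower and 2 at least 2-fold higher in the library labelled UUO. Cnn1 was 2.08-fold (1.70 to 2.52) higher there without the added 5. The contractile median moved to -0.999 with each library clustered on its own and to -0.67 in fibroblast-like cells only. Tpm1 and Tagln were 3.31-fold (3.17 to 3.47) and 2.44-fold (2.34 to 2.55) higher in the library labelled sham. Myh11 and Lmod1, of differentiated smooth muscle, were 3.34-fold (2.82 to 3.93) and 4.71-fold (3.86 to 5.71) higher in the library labelled UUO. The mural identity list had a median of 1.67 (1.51 to 1.87), or 0.97 with 20 CPM added. On ratios with 5 CPM added, 7 of 9 members were at least 2-fold higher in the library labelled UUO. Without the added 5, Rgs5 was 6.56-fold (6.11 to 7.04), Kcnj8 8.01-fold (7.03 to 9.12) and Mcam 2.12-fold (1.67 to 2.67) higher there. Pericyte- or smooth muscle-like cells were 39 of 688 mesenchymal cells labelled UUO and 39 of 7340 labelled sham. Without them the log2 ratio of Myh11 was -0.17, that of Notch3 moved from 0.43 to -0.052, and the list median was 1.46. With 39 cells each, below the minimum of 50, the mural-like class was not compared on its own.

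Signalling lists were mixed. TGF-beta response genes had a median of -0.46 (-0.60 to -0.35), at the 0.41st percentile, with 5 of 15 at least 2-fold lower and 3 at least 2-fold higher, and their extremes were Inhba and Ltbp2 on one side and Ccn2 and Tgfbi on the other. Tgfbi was 2.62-fold (2.48 to 2.77) higher in the library labelled UUO. WNT pathway genes had a median of -0.20 (-0.30 to -0.14), at the 20.7th percentile, which moved between -0.38 (own clusters) and -0.027 (equal weight for each cell). Of 15 members, 3 were lower and 5 higher by at least 2-fold with 5 CPM added. Axin2 was 2.64-fold (1.72 to 4.29) higher in the library labelled sham without the added 5. Beside Nkd2, the receptor gene Fzd1 was 2.97-fold (2.72 to 3.25) higher in the library labelled sham, while the secreted modulators Sfrp2 and Sfrp4 were 11.2-fold (10.3 to 12.3) and 30.0-fold (28.6 to 31.4) higher in the library labelled UUO. The list of PDGF and gate genes lay at 0.08 (-0.059 to 0.19), the 76.1st percentile, and was at -0.35 with own clusters. Of 8 members, 1 was higher and 1 lower by at least 2-fold with 5 CPM added. Gli1 was 2.21-fold (1.68 to 2.88) higher in the library labelled UUO without the added 5. Thy1 was 5.56-fold (4.91 to 6.33) higher in the library labelled sham and Cd34 6.18-fold (5.72 to 6.67) in the library labelled UUO.

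Complement genes were higher in the library labelled UUO, with 7 of 9 members at least 2-fold higher and a median of 2.06 (1.87 to 2.14), above all random lists, which moved to 1.32 after thinning. The central component C3 was 15.7-fold (14.8 to 16.6) and the regulator Cd55 11.5-fold (9.68 to 13.7) higher. Chemokines and cytokines had a median of 0.56 (0.40 to 0.69), at the 99.5th percentile. Of 16 members, 6 were at least 2-fold higher and 1 at least 2-fold lower with 5 CPM added. Csf1 was 2.05-fold (1.82 to 2.30) higher in the library labelled UUO without the added 5. The chemokine median moved to 0.14 with all retained cells, 0.35 with 20 CPM added, and 0.85 and 0.19 in cells with Xist and with Y-linked UMIs. Ccl11, the eosinophil attractant, was 14.0-fold (13.3 to 14.8) higher, while the neutrophil attractant Cxcl5 had 896 counts in the library labelled sham and 1 in the library labelled UUO. C3, like Sfrp4, was among the leading genes of clusters 11 and 13, and Ccl11, like Car3, of clusters 22 and 28. The shares of such cells were not separated from the levels here either. Interferon response genes had a median of 0.42 (0.30 to 0.48), at the 98.1st percentile, with 1 of 14 at least 2-fold higher, Irf1 at 3.41-fold (3.15 to 3.69). It moved to 0.20 with own clusters, 0.25 in cells with Xist UMIs and 0.26 with 20 CPM added. Antigen presentation genes also lay at 0.42 (0.38 to 0.51), the 98.1st percentile. There the class I genes H2-D1 and H2-Q7 were 3.16-fold (3.11 to 3.22) and 4.62-fold (3.94 to 5.40) higher in the library labelled UUO, although reads of such related genes can be shared. The class II genes Cd74 and H2-Eb1 were 2.60-fold (2.23 to 3.05) and 3.23-fold (2.26 to 4.77) higher in the library labelled sham. Macrophage or dendritic markers were 2.66-fold higher in the same cells. Cd74 is itself 1 of those markers and made 99.3 of their 251 CPM labelled sham and 38.2 of 94.3 labelled UUO. The class II difference is not read as one of fibroblasts.

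Stress and metabolism lists went both ways. Heat shock genes had a median of 0.67 (0.61 to 0.70), at the 99.3rd percentile, and 0.42 in cells with Y-linked UMIs. With 5 CPM added, 1 of 10 members was at least 2-fold higher, Dnajb1. Without the added 5, Dnajb1 was 2.93-fold (2.79 to 3.08) and Hsph1 2.40-fold (1.98 to 2.90) higher in the library labelled UUO. Immediate early genes, which respond within minutes to handling of tissue, had a median of 0.28 (0.26 to 0.30), at the 98.3rd percentile, which moved to 0.65 with each library clustered on its own and to 0.034 after thinning to 1000 UMIs. Atf3 was 4.47-fold (4.25 to 4.69) higher in the library labelled UUO. Lipid handling and metallothionein genes had a median of 0.84 (0.67 to 0.96), at the 99.9th percentile, which moved to 0.51 after thinning, with Apoe 3.45-fold (3.40 to 3.50) higher. Secretory pathway and unfolded protein genes lay at 0.22 (0.17 to 0.26), the 98.7th percentile, with the chaperone gene Hspa5 2.03-fold (1.964 to 2.10) higher. Glycolysis and hypoxia genes lay at -0.24 (-0.37 to -0.13), the 16.6th percentile, moving between -0.40 (equal weight for each cell) and -0.042 (all retained cells), although Adm, a hypoxia-induced vasodilator peptide gene, was 12.1-fold (11.4 to 12.9) higher in the library labelled UUO. Nuclear genes of oxidative phosphorylation lay at -0.056 (-0.15 to 0.026), the 74.8th percentile, or 0.21 with all retained cells, and all 17 were within 2-fold. Cell cycle genes had 8 measured members and a median of -0.39 (-0.59 to -0.19), at the 3.12th percentile. No direction is read from it, since the sign turned in 6 alternatives and, with median-of-ratios scaling, only because other members passed 10 CPM. Stmn1 was 4.83-fold (3.89 to 6.07) higher in the library labelled sham.

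**Figure D3:**
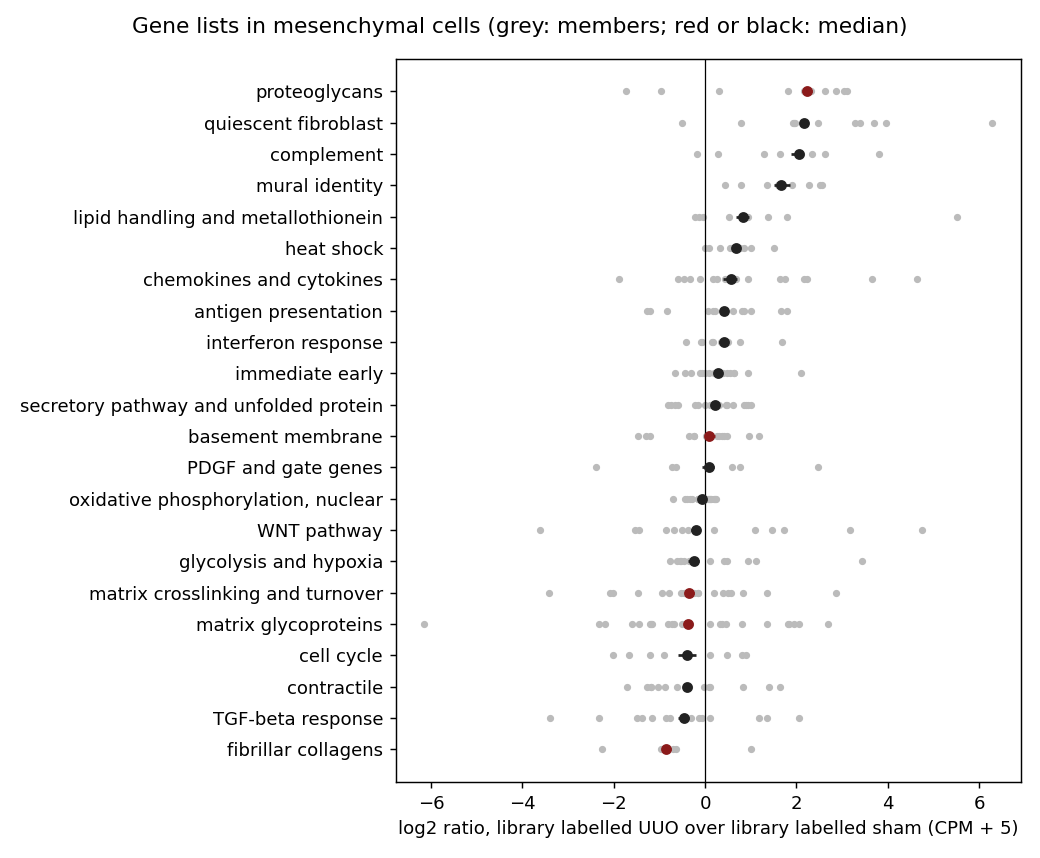
Log2 ratio of the library labelled UUO over the library labelled sham (CPM + 5, horizontal axis) for the members (grey points) of each gene list fixed in advance (vertical axis) in mesenchymal cells. Red (matrix lists) and black (other lists) points are list medians with their counting interval, from 2.24 for proteoglycans at the top to -0.84 for fibrillar collagens at the bottom.

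Markers of other cell types were also counted in the mesenchymal cells, and several differed between the libraries. The summed markers of proximal tubule stood at 3589 CPM in the library labelled UUO and 1095 CPM in the library labelled sham, a ratio of 3.28 (3.22 to 3.33), of which Gpx3 alone made 2692 and 1028 CPM. Of the other proximal tubule markers, Ass1 differed less, at 82.8 against 52.6 CPM, and Miox and Kap more, Miox at 308 against 5.88 CPM and Kap at 359 against 5.12 CPM. Erythroid markers stood at 352 and 19.4 CPM, 18.2-fold (16.8 to 19.6) higher in the library labelled UUO. Loop or distal tubule markers were 2.09-fold (1.83 to 2.37), glial markers 9.20-fold (6.93 to 12.2) and B cell or plasma cell markers 3.14-fold (2.16 to 4.46) higher there, the last from 39 against 179 counts. Injured tubule markers were 61.3-fold (57.5 to 65.5) higher in the library labelled sham, at 13067 against 213 CPM, of which Spp1 alone made 13017 and 178. Macrophage or dendritic markers were 2.66-fold (2.41 to 2.94), T or NK markers 2.27-fold (1.28 to 4.43), proliferation markers 2.92-fold (2.51 to 3.42) and neutrophil markers 1.21-fold (1.15 to 1.28) higher in the library labelled sham. Of the proliferation marker counts, Stmn1 alone made 5770 of 7240 labelled sham and 83 of 172 labelled UUO. No difference in proliferation is read from that sum. Endothelial markers were 1.21-fold (1.15 to 1.28) higher in the library labelled UUO. The ratios UUO over sham as labelled were 1.06 (0.899 to 1.25) for collecting duct, 0.919 (0.829 to 1.02) for podocyte and 1.58 (0.698 to 3.15) for mesothelial or urothelial markers, with intervals that include 1.

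Cells with and without an Nkd2 UMI were compared within each library, to see whether the gene marks cells rich in matrix transcripts. The difference turned without Spp1 in the library labelled sham. Its sign also changed at equal depth in the library labelled UUO, where only 9 Nkd2-detecting cells were left. Nkd2 UMIs were found in 52.3% (51.2 to 53.5) of mesenchymal cells labelled sham and 5.09% (3.57 to 7.004) of those labelled UUO. In endothelial-like cells they were found in 9.91% (7.23 to 13.2) of cells labelled sham and in 0 of 78 labelled UUO. Thinned to 1000 UMIs, the mesenchymal shares were 13.0% (12.2 to 13.8) and 1.36% (0.622 to 2.56). In the library labelled sham, 7.52% of the UMIs of Nkd2-detecting mesenchymal cells came from the 86 matrix genes, against 6.41% in cells without an Nkd2 UMI. The difference of 1.10 percentage points (1.09 to 1.12) lay at the 99.7th percentile of 3696 genes detected in a like share of cells, and it was 1.22 points (1.16 to 1.28) at equal depth. With Spp1 left out, an alternative added after the data were seen, the difference was -0.19 points (-0.20 to -0.18), at the 29.7th percentile, and -0.21 points (-0.26 to -0.16) at equal depth. In the library labelled UUO the difference was 0.36 points (0.28 to 0.45) over 35 Nkd2-detecting cells, at the 80.2nd percentile, and 0.29 points (0.21 to 0.37) without Spp1. At equal depth it was -0.88 points (-1.30 to -0.46), at the 15.3rd percentile of comparison genes, from 9 cells. The interval leaves out the spread between cells, so no direction is read from these 9 cells.

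At equal depth in the library labelled sham, Nkd2-detecting cells had 2.44-fold (2.41 to 2.48) more Spp1, at 24165 against 9885 CPM. They also had 2.89-fold (1.503 to 5.33) more Pdgfc, a PDGF ligand gene, 2.08-fold (1.06 to 3.86) more Lef1, a WNT effector gene, 1.75-fold (1.32 to 2.29) more Ltbp2 and 1.54-fold (1.43 to 1.66) more Timp1. Spp1, Nkd2, Timp1 and Ltbp2 were all among the 10 leading genes of cluster 4, which held 1078 cells labelled sham. Whether these differences go beyond membership of that cluster was not tested. Median log2 ratios of the matrix lists, with over without Nkd2, ran from -0.20 for proteoglycans to -0.031 for fibrillar collagens, and no fibrillar collagen differed by 1.5-fold. Quiescent fibroblast genes had a median of -0.51 and chemokines and cytokines of -0.56. With 5 CPM added, as for all counts of members here, 5 of 12 and 7 of 15 were at least 1.5-fold lower and 1 higher in each. Without the added 5, the ratios of Dpt, Ccl7 and Ccl2 were 0.665, 0.662 and 0.659. TGF-beta response genes had the highest median, 0.28, with 1 of 15 members at least 1.5-fold higher and 1 lower. WNT pathway genes lay at -0.10, with Lef1 higher and Sfrp2 and Sfrp4 lower. Cxcl12, a chemokine gene, stood at 261 CPM in Nkd2-detecting cells and 629 CPM in the others, and C3 at 9.45 and 36.1 CPM.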

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

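The reporter entry eGFP was counted in 91.9% of mesenchymal cells of the library labelled sham and in 77.9% of those of the library labelled UUO, although the labels used here name no reporter strain. It stands here because no comparison of the report used it. In endothelial-like cells the shares were 27.8% and 19.2%, and the difference between the libraries was not tested.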

How the results depend on the processing

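The alternatives with Xist cells, with Y-linked cells, without genes of other cell types, with clusters 7 and 8 and without Spp1 were chosen after the data were seen. With 1 library per group, none of them replaces a replicate. Of the values of single genes, 1449 kept their size, 471 moved and 6 turned, and of list medians 291 kept their size, 101 moved and 9 turned. No scaling shifted the median of all genes by more than 0.10, and no alternative turned the fibrillar collagens, proteoglycans, matrix glycoproteins or crosslinking genes.

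The mesenchymal share in the library labelled sham was 78.8% with at least 1000 UMIs per cell, 82.8% at the mitochondrial limit of 10%, 82.9% at resolution 0.5 and 88.4% with clusters 7 and 8. In the library labelled UUO it was 76.2% with at least 1000 UMIs, 44.9% with each library clustered on its own and 52.9% without a cell filter. The macrophage-like share labelled UUO was 0% with own clusters and 0.542% without a cell filter. Proximal tubule-like shares ran from 0.239% (mitochondrial limit of 10%) to 0.533% (resolution 0.5) labelled sham. Labelled UUO they ran from 5.61% (mitochondrial limit of 10%) to 11.6% (at least 1000 UMIs). The Pdgfra share labelled sham was 76.5% at the mitochondrial limit of 10%, 79.1% without doublet removal and 21.9% thinned, and labelled UUO 22.3% thinned. The Pdgfrb share labelled sham was 84.2% without doublet removal and 27.0% thinned, and labelled UUO 17.0% thinned.

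The matrix difference of Nkd2-detecting cells labelled sham was 1.07 points with at least 1000 UMIs, 1.01 without doublet removal and 1.22 thinned. It turned to -0.19 without Spp1 and -0.21 without Spp1 and thinned. Labelled UUO it turned to -0.88 thinned, and -0.88 thinned without Spp1, both from 9 Nkd2-detecting cells.

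Fibrillar collagens moved to -0.66 (own clusters), -1.01 (mean over cells), -1.01 (all cells) and -0.69 (Xist cells). Proteoglycans moved to 2.52 (own clusters), 2.03 (mean over cells), 2.05 (thinned), 2.56 and 1.66 (1 and 20 CPM added), 2.08 (all cells), 2.39 (Xist cells) and 2.12 (Y-linked cells). Matrix glycoproteins moved to -0.34 (own clusters), -0.33 (median of ratios), -0.54 (mean over cells), -0.54 (thinned), -0.47 (all cells), -0.48 (Xist cells) and -0.60 (Y-linked cells). Crosslinking and turnover genes moved to -0.46 (mean over cells), -0.48 (thinned), -0.44 (all cells) and -0.17 (Xist cells).

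Basement membrane genes turned to -0.23 (own clusters), -0.13 (thinned) and -0.14 (Y-linked cells). Cell cycle genes turned to 0.14 (median of ratios, a shift of 0.048 per gene, so by a change in which members passed 10 CPM), 0.24 (mean over cells), 0.52 (thinned), 0.10 (fibroblast-like cells), 0.26 (without mitochondrial and ribosomal genes) and 0.00019 (Y-linked cells). Among single genes, log2 ratios turned for Hsp90ab1 (-0.013, thinned), Mt2 (0.098, own clusters), Myh11 (-0.17) and Notch3 (-0.052) in fibroblast-like cells, and Pdgfra (-0.088 with own clusters, -0.064 with all cells).

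Lists whose interval holds 0 also changed sign: oxidative phosphorylation to 0.21 (all cells), PDGF and gate genes to -0.35 (own clusters) and -0.12 (mean over cells). Further moves by over 1.5 times, without a turn, included WNT genes to -0.027 (mean over cells), chemokines to 0.14 (all cells), complement to 1.32 (thinned), Acta2 to -2.17 (fibroblast-like cells) and Pdgfrb to -1.34 and Col1a1 to -0.32 (own clusters).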

Other observations

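Tubule cells that came through the sort also differed between the libraries. In the proximal tubule-like cells of cluster 16, Havcr1, the gene of a kidney injury molecule of the proximal tubule, had 29 UMIs in 35 cells labelled sham and 0 in 82 labelled UUO. The ratio per UMI was 11.7 with the 0 set against 3 counts, and its exact lower limit was 8.94. Spp1 was 24.4-fold (22.3 to 26.8) and Clu 19.4-fold (7.98 to 61.4) higher there in the library labelled sham. In tubule cluster 12, Lcn2, which injured distal tubule releases, had 8321 UMIs in 239 cells labelled sham and 0 in 16 labelled UUO. The ratio was 44.2 on the same floor, with an exact lower limit of 35.9. These cells passed a sort for other cells, in small numbers and from 1 library each, and free RNA in them was not tested.

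The sex chromosome list had a median log2 ratio of 0.68 (0.54 to 0.81), at the 94th percentile, with 4 measured members. Xist, which coats the inactive X chromosome of female cells, stood at 862 CPM in the library labelled sham and 321 in the library labelled UUO. The other 3 members, the Y-linked Uty, Ddx3y and Eif2s3y, were 4.18-fold (3.41 to 5.11), 1.99-fold and 1.49-fold higher in the library labelled UUO.

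The tests of exchanged labels, depth and free RNA were set down before their results were seen, but after the pattern itself and the other main results were known, and those on Xist and Y-linked genes after. Fibrillar collagen genes were lower and quiescent fibroblast genes higher in mesenchymal cells of the library labelled UUO, the reverse of what obstruction is known to do, although the fibrosis-associated Ccn2 and Postn were 4.26-fold and 1.80-fold higher there. The summed injury genes Havcr1, Lcn2, Krt20 and Clu were 2.42-fold (2.08 to 2.83) higher in the library labelled sham in cluster 12 and 20.1-fold (9.45 to 51.1) in cluster 16, so exchanged labels could explain the pattern. In cluster 16 the sum was 116 UMIs labelled sham against 7 labelled UUO, of which Clu made 80 and 5. Free RNA in these tubule cells was not tested. The gap between the list medians was 3.01 after thinning, against 3.01 without it. Thinning was done on cells classed at full depth and leaves shares of a summed total nearly unchanged. It therefore cannot decide whether fewer UMIs per cell acted through clustering and class names, which stays open. Free RNA of other cell types stays open, because leaving out 780 such genes, with a gap of 3.01, moved no result and so tested nothing. A real effect of the labelled condition, or differences between animals or preparations, stays open and untested with 1 library per group. So does a difference in the mix of fibroblast-like clusters.

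Cells with Xist UMIs and cells with Y-linked UMIs were found in both libraries. Among cells with at least 5000 UMIs, 61.8% labelled sham and 36.3% labelled UUO had at least 2 Xist UMIs, and 14.8% and 26.6% at least 2 Y-linked UMIs. Both kinds met in the same cell at 0.189 (0.155 to 0.228) of the rate of independent draws in the library labelled sham and 0.350 (0.196 to 0.577) in the library labelled UUO. This argues against free RNA in cells of 1 sex and is consistent with female and male animals pooled in each library. The number of animals per library stays open.

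Proximal tubule genes were counted in mesenchymal cells of the library labelled UUO. Of 9 proximal tubule markers, 7 lay within 2-fold between its mesenchymal and endothelial-like cells, among them Miox at 308 and 511 CPM and Kap at 359 and 395 CPM, so free RNA from proximal tubule could account for them. The count of 7 sits on the limit set for this test, with Gpx3 just inside it at 2692 and 1354 CPM and Cubn resting on 2 endothelial counts. Mixed droplets are argued against by the spread, since 93.3% (91.2 to 95.1) of its mesenchymal cells held a UMI of a proximal tubule marker other than Gpx3, against 34.2% (33.1 to 35.3) labelled sham. Leakage during digestion and tubule damage before it stay open.

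Dlk1, Mest, Meg3 and Gpc3, most of them imprinted genes active in growing tissue, were higher in the library labelled UUO, Mest at 85.8 against 2.02 CPM and Gpc3 at 669 against 28.9 CPM. As a hypothesis, that tissue could come from a younger animal. Gpc3 was among the leading genes of cluster 11 (276 cells labelled UUO, 0 labelled sham), and Meg3 of cluster 13 (1 and 190). A difference in the mix of fibroblast-like clusters was not separated from age and stays open. The 8 other measured genes of the imprinted growth network had a median log2 ratio of 0.59, at the 97.6th percentile of random lists, barely past the limit set before the test, by when the 4 genes and Cdkn1c had been seen. Gnas went the other way at -0.17, and Igf2, H19 and Slc38a4 were under 10 CPM in both libraries and so not among the 8. Plagl1 passed that filter only in the library labelled UUO, at 13.3 against 2.16 CPM, so the percentile depends in part on the filter.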
